A study of Rattus norvegicus with 12 samples.

How the data were processed

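Total RNA of 6 INS-1 clones was measured on 12 rat expression arrays, 1 array per clone without tetracycline and 1 with it. INS-1 is a rat insulinoma line that makes insulin. Per the labels, each clone carried an HNF1b construct (hepatocyte nuclear factor 1b, a transcription factor) at a recombination site, switched on by tetracycline. The constructs were wild-type HNF1b (clones 1a and 2b) and the mutants P328L329del (clones 5a and 6a) and A263insGG (clones 3b and 4a), which the labels give as mutants found in MODY5, a form of diabetes.

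The deposited values were intensities per probe set on a linear scale. Every array had a 2% trimmed mean of 1000, so the authors had scaled each array to a common mean. The authors' tool for making the values was not given in the sources used here. The file held no detection calls. Array medians lay between 326.9 and 370.6 (highest over lowest 1.13), so the authors' scaling was kept. The number of arrays limits the precision, and p-values measure only the spread between these clones.

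Values were taken as log2 after adding 62.2, the 20th percentile of all values. Of 15923 probe sets, 57 control probe sets were left out, and of the remaining 15866 the 9520 whose mean reached the 40th percentile were tested. limma 3.58.1 in R 4.3.3 was fitted to all 12 arrays with clone as a block and 1 induction effect per construct (residual degrees of freedom 3, prior degrees of freedom 5.49). Uninduced clones were compared in a fit with 6 groups and no block, because clones are nested in constructs (6 and 5.61). Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p below 0.05. Log2 changes are given with their standard error (SE) from the fit.

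The labels name the same clone, and so the same cell line, on its uninduced and induced arrays, which is why clone was a block. As a check on the pairing, the deviations of a clone's 2 arrays from their group means were correlated across probe sets. The r was 0.227 for wild-type, 0.337 for P328L329del and 0.16 for A263insGG. These r are across genes, which are not independent replicates.

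Gene symbols came from the probe table supplied with the data. It named 13101 probe sets, 12789 of them with 1 symbol and 312 with several, and 2771 had no name there. Of the probe sets with 1 symbol, 12754 matched the supplied rat gene table by gene identifier and 0 symbols changed. Among the tested probe sets 8118 had 1 symbol, for 6977 genes. Hnf1b and Hnf1a were named by 0 probe sets, so the level of the introduced gene could not be read. Coordinates were not used.

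The comparisons of genes and gene lists, their limma, camera and fry tests, the lists and the alternatives were fixed before the data were examined. The sign-flip test of the lys control and part of the tests in the closing section were chosen later. The 30 gene lists held 868 genes, of which 707 were on the array and 500 were tested. A gene was represented by its probe set of highest mean. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists, and again with an estimated correlation and with fry, which tests a list by itself. With an estimated correlation 0 lists passed in each of the 10 comparisons.

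Genes were named by a rule. For each induction and for the mean effect, these were the 12 largest rises and the 12 largest falls that passed and went the same way in both clones (at least 5 of 6 for the mean effect). For each difference and each uninduced comparison, the 6 largest in each direction were named, or the 5 with the smallest p where fewer than 5 passed. From each list that passed, the 4 members with the smallest p were named, and passing members of the HNF1 target, beta-cell and islet hormone lists. The rule also asked for Hnf1b and Hnf1a. Ins1, Ins2 and members of lists that did not pass were named after their values were seen.

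Besides limma's test, probe sets with a change of 2-fold or more in the same direction in both clones were counted, with pairs of clones from different constructs as the comparison. Induction effects were correlated across genes between all pairs of clones. Counts of called probe sets were recomputed with an offset of 1 or at the 40th percentile, no filter, a filter at the 60th percentile, quantile normalization, eBayes with trend and robust settings, and without each clone in turn. Those of the inductions, the mean effect and the differences were also recomputed with no clone block and with clone as a random block, and those of the inductions with the arrays of that construct alone. The other counts had part of these alternatives. The mean effect was also fitted as 1 induction term over 6 clones.

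The fit was tested on simulated data with 9520 probe sets, of which 200 were changed in the wild-type clones. Of the changes of 1.5-fold 44% were recovered, of those of 2-fold 94%, and of those of 3-fold and 4-fold 100%. The difference P328L329del minus wild-type recovered 8%, 70%, 94% and 100% of the same changes. Of 188 simulated calls 19 were for unchanged probe sets, and 1 probe set was called for A263insGG and 0 for P328L329del, where limma had no change to find. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.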

Results

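Gene expression was measured as deposited intensity in 6 clones of INS-1, a rat insulinoma line, each with and without tetracycline induction of an HNF1b construct. Wild-type HNF1b, the mutant P328L329del and the mutant A263insGG were each carried by 2 clones, which gave 6 groups of 2 arrays. Ins1, an insulin gene, had the highest mean intensity on the arrays, at 37500 ± 3850 (SD, n = 2 clones) in uninduced wild-type clones. Across the 12 arrays the ratio of the 3' to the 5' control probe set of GAPDH lay between 0.961 and 1.07, and array pairs correlated at r = 0.915 to 0.991 across genes. The lys control, an RNA added during preparation, was lower on the induced array in 6 of 6 clones, by -1.69 ± 0.289 on the log2 scale (SD, n = 6 clones, exact two-sided sign-flip p = 0.0312, the smallest that 6 clones allow).

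Induced and uninduced cells of each clone were compared to find genes that respond to the introduced factor. With wild-type HNF1b, Ubd, which encodes a ubiquitin-like protein, rose from an intensity of 156 ± 1.27 to 10900 ± 170 (SD, n = 2 clones), a log2 change of 5.65 ± 0.22 (SE, limma adjusted p = 3.5e-06). Car2, a carbonic anhydrase, rose by 4.91 ± 0.25 on the log2 scale, and Folr1, a folate receptor, by 4.49 ± 0.25. The 12 largest rises also held log2 changes of 3.24 ± 0.10 for Slc3a1, a subunit of a cystine transporter, and 3.02 ± 0.14 for Gsta1, a glutathione transferase. Rises of this order were also measured for Fhit (4.06), Cyp4f1 (4.02), Fzd1 (3.97), Ctsc (3.92), Rup2 (3.34), Nr1h4 (2.83) and Apcs (2.52). The largest fall was that of C2cd4b, from 1370 ± 65.1 to 23.9 ± 2.26 (log2 change -4.06 ± 0.10, limma adjusted p = 6.5e-07). Induced levels of C2cd4b, Wnt4, Cyp4a8, Eef2k and Gpr6 were below 62.2, the value added before taking logs, so the size of their falls depends on it. Kcnj11, the pore subunit of the ATP-sensitive potassium channel, fell by 3.30 ± 0.12 on the log2 scale, and Pdx1, a transcription factor of beta cells, went from 4040 ± 174 to 528 ± 131 in intensity. Falls of this order were also measured for Scn3a (-3.37), Wnt4 (-3.28), Ngfr (-3.06), Stc1 (-3.0), Cyp4a8 (-2.86), Eef2k (-2.72), Gpr6 (-2.71), Igfbp3 (-2.65) and Mylk (-2.46). A second probe set of Eef2k fell by 0.85 on the log2 scale, less than the first. The rule that named these 24 genes required the same direction in both clones. In all, 1304 probe sets rose and 1625 fell by limma with Benjamini-Hochberg adjustment, 2929 of 9520, and 241 of the rises and 285 of the falls were 2-fold or more. By size alone, 192 probe sets were 2-fold higher and 225 were 2-fold lower in both clones, 417 in all, against a mean of 9.5 for 12 pairs of clones of different constructs. Without clone 1a the count of calls was 1276, and without clone 2b it was 1441.

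Genes reported as HNF1 targets in liver, kidney and islets rose as a list with wild-type HNF1b. Of 15 tested members 7 rose, 2 fell and 6 did not pass (8 rises and 2 falls adjusted over the list alone). The camera adjusted p was 0.006, and the adjusted p = 0.29 with an estimated correlation. Nr1h4, the bile acid receptor, rose from 399 ± 52.5 to 3210 ± 67.7 in intensity (SD, n = 2 clones). Crp, an acute-phase protein, rose by 2.18 ± 0.16 on the log2 scale, Ttr, a thyroid hormone carrier, by 2.16 ± 0.12 and Cltrn, collectrin, by 2.02 ± 0.12. Pklr, a pyruvate kinase, rose by 1.07 ± 0.11, Gc by 0.86 ± 0.14 and Kif12 by 0.42 ± 0.11. Slc2a2, a glucose transporter, fell by 0.72 ± 0.14 and Fgg, a fibrinogen chain, by 0.46 ± 0.13. Without clone 1a the calls of Slc2a2, Fgg and Kif12 were lost, without clone 2b those of Fgg and Kif12, and without clone 5a or 6a that of Fgg.

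**Figure D1:**
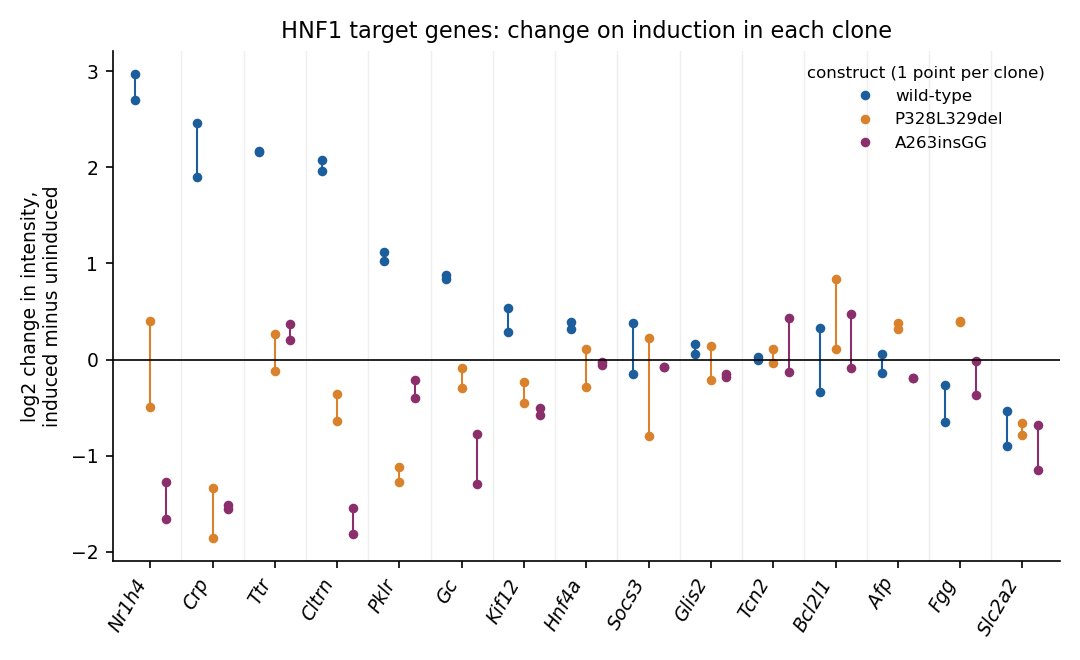
Log2 change in intensity, induced minus uninduced, of the 15 tested HNF1 target genes, with 1 point per clone joined by a line within a construct. Nr1h4 changed by 2.83 with wild-type HNF1b and by -1.47 with A263insGG.

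Genes of beta-cell identity and insulin secretion fell with wild-type HNF1b: 18 of 24 tested members fell, 1 rose and 5 did not pass (18 falls and 2 rises adjusted over the list alone). Their median log2 change was -0.93 (camera adjusted p = 2.6e-08, adjusted p = 0.28 with an estimated correlation). Transcription factors of beta cells fell beside Pdx1 (-2.81 ± 0.14), with log2 changes of -1.73 ± 0.18 for Isl1, -1.63 ± 0.11 for Pax6, -1.62 ± 0.10 for Nkx6-1 and -0.48 ± 0.14 for Neurod1. Abcc8, the regulatory subunit of the ATP-sensitive potassium channel, fell by 1.60 ± 0.11. Receptors for the incretin hormones fell too, Gipr by 1.60 ± 0.13 and Glp1r by 1.42 ± 0.11. Sytl4 (-1.99), Ero1b (-1.61), Pcsk2 (-1.34), Prlr (-0.97), Pam (-0.88), Ptprn (-0.80), Iapp (-0.62) and Cacna1c (-0.53) fell as well, and Glul rose (0.62). Another Prlr probe set had a log2 change of 0.23 (limma adjusted p = 0.28) and a further one -0.59 (0.0064). The insulin genes did not pass, with log2 changes of 0.26 for Ins1 and 0.17 for Ins2, but Ins1 was the brightest probe set and saturation at the top of the scale was not tested. Prlr and Cacna1c lost their calls without either wild-type clone, Glul and Slc2a2 without clone 1a and Neurod1 without clone 2b, 5a or 6a.

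**Figure D2:**
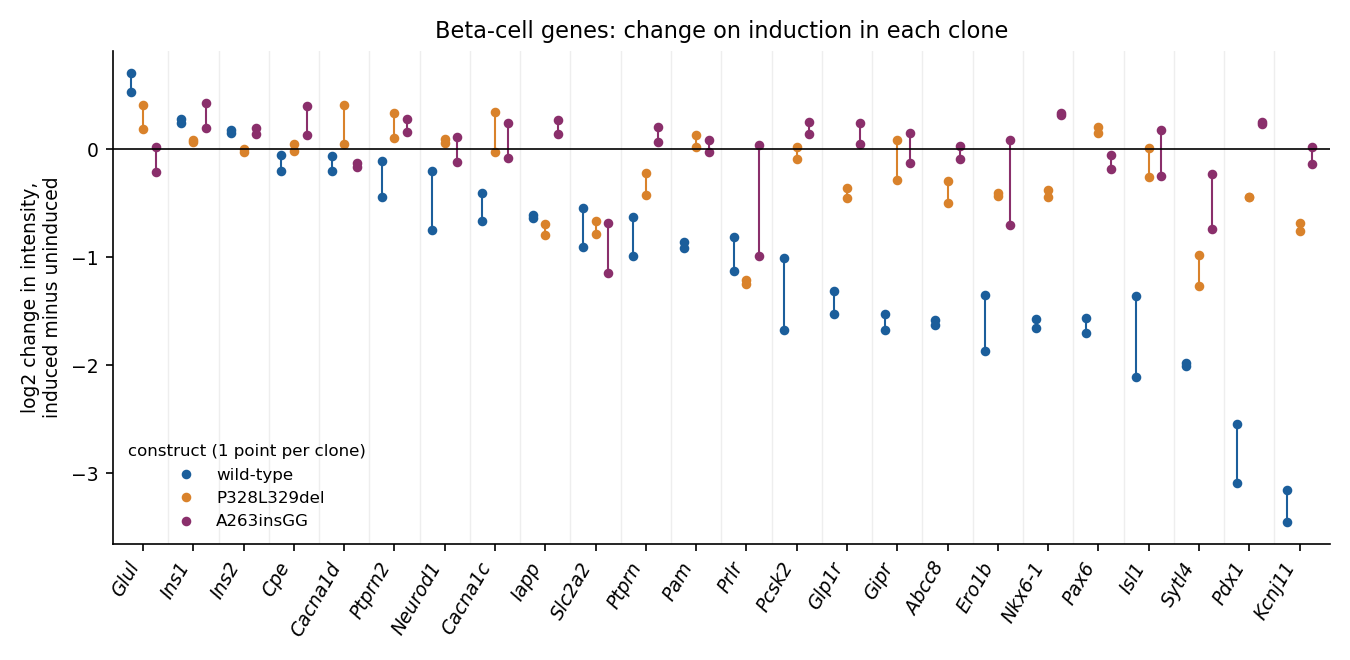
Log2 change in intensity, induced minus uninduced, of the 24 tested genes of beta-cell identity and insulin secretion, with 1 point per clone joined by a line within a construct. Kcnj11 changed by -3.30 with wild-type HNF1b and by -0.72 with P328L329del.

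Other endocrine genes and the secretory machinery fell with wild-type HNF1b. Of 5 tested islet hormone genes 4 fell, over all tests and adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.33 with an estimated correlation). These were Gcg, glucagon (-1.95 ± 0.10), Gast, gastrin (-0.67 ± 0.12), Cartpt (-0.44 ± 0.13) and Npy, neuropeptide Y (-0.33 ± 0.11). Of 24 tested genes of granins and exocytosis 14 fell and 2 rose (16 and 3 adjusted over the list alone), with log2 changes of -1.64 for Syt5, -1.42 for Rab3b, -1.23 for Vgf and 0.98 for Rims2. That list had a camera adjusted p of 0.00044 (adjusted p = 0.28 with an estimated correlation). Npy lost its call when any 1 of the 6 clones was left out, Cartpt without clone 1a or 2b, and Gast without clone 2b.

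Lists of stress and growth genes fell in part with wild-type HNF1b. Of 25 tested genes of ER stress and the unfolded protein response 13 fell and 1 rose, over all tests and adjusted over the list alone (camera adjusted p = 0.0024, adjusted p = 0.28 with an estimated correlation), among them the chaperones Hspa5 (-0.95), Hsp90b1 (-0.89) and Dnajb11 (-0.65). Of 19 tested genes of the amino acid response 9 fell and 3 rose, on either adjustment (camera adjusted p = 0.048, adjusted p = 0.33 with an estimated correlation), with log2 changes of -1.50 for the transporter Slc7a5, -1.19 for Nupr1, -0.88 for Atf5 and -0.87 for Cebpb. Of 18 tested genes of cholesterol synthesis and uptake 7 fell, also adjusted over the list alone (camera adjusted p = 0.025, adjusted p = 0.33 with an estimated correlation), with log2 changes of -1.70 for Mvd, -1.0 for Sqle, -0.88 for Idi1 and -0.81 for Msmo1. The second Idi1 probe set changed by -0.21 (limma adjusted p = 0.23). Of 22 tested genes of DNA replication 7 fell, also adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.33 with an estimated correlation), such as Pola1, a DNA polymerase subunit (-1.0), Ccne2, cyclin E2 (-0.75), and Mcm5 of the replicative helicase (-0.55). The call of the amino acid list was lost on leaving out any of the 6 clones, that of DNA replication without clone 1a and that of cholesterol synthesis without clone 2b.

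Lists that rose with wild-type HNF1b, beside the HNF1 targets, held genes of inflammation, antioxidant defence and oxidative metabolism. Of 9 tested genes of NF-kappaB and the acute phase 6 rose (7 adjusted over the list alone), with log2 changes of 1.06 for Nfkb2, 0.85 for Relb, 0.81 for Nfkbia and 0.59 for Nfkb1 (camera adjusted p = 0.0013, adjusted p = 0.33 with an estimated correlation). Of 13 tested interferon response genes 5 rose, also adjusted over the list alone (camera adjusted p = 0.025, adjusted p = 0.38 with an estimated correlation), with 0.74 for Stat2, 0.69 for Irf1, 0.54 for Psmb9 and 0.43 for Psmb10. The second Stat2 probe set gave 0.75 (limma adjusted p = 0.093). Of 21 tested oxidative stress genes 8 rose, also adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.38 with an estimated correlation). Those 8 included enzymes of glutathione metabolism, with 2.04 for Gclc and 0.96 for Gsta4, and Ephx1, an epoxide hydrolase (1.05). Of 36 tested genes of oxidative phosphorylation 6 rose (1 adjusted over the list alone), such as Ndufb8 (0.85) and Ndufa5 (0.50), with a camera adjusted p of 0.016 (adjusted p = 0.44 with an estimated correlation). Of 26 tested genes of cytosolic ribosomal proteins 0 passed in limma, over all tests or adjusted over the list alone, and the list's camera adjusted p was 0.023 (adjusted p = 0.38 with an estimated correlation). A second probe set of Rps24, outside the list test, fell (-0.48, limma adjusted p = 0.026), against 0.25 for the one in the list. The calls of the oxidative phosphorylation, ribosomal and amino acid lists were lost with quantile normalization (camera adjusted p = 0.11, 0.61 and 0.075). Leaving out clone 1a ended the call of the interferon list, and leaving out clone 2b those of oxidative phosphorylation and ribosomal proteins. In all 13 of 30 lists passed with wild-type HNF1b, 6 of them higher.

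**Figure D3:**
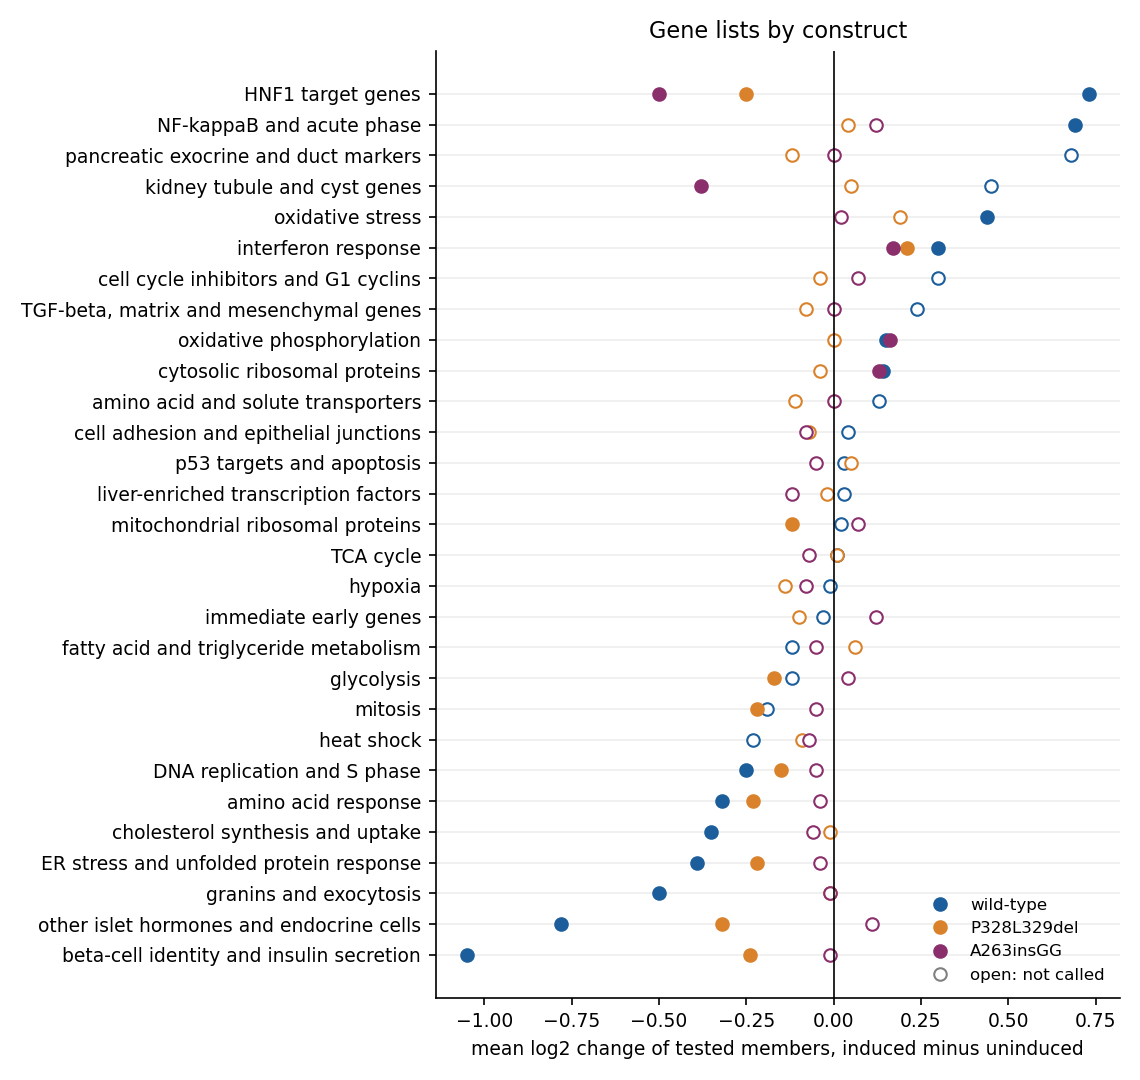
Mean log2 change in intensity, induced minus uninduced, of the tested members of 29 gene lists with each construct, where filled points are lists that passed camera at a preset correlation and open points did not. Cytosolic ribosomal proteins turn direction with A263insGG under quantile normalization (camera adjusted p = 0.64).

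Induction of P328L329del lowered Ddc, the decarboxylase that makes dopamine and serotonin, from 1580 ± 195 to 213 ± 66.1 in intensity (SD, n = 2 clones), a log2 change of -2.60 ± 0.12 (SE, limma adjusted p = 9.1e-05). Myc, a growth-promoting transcription factor, fell by 1.88 ± 0.16, and Angptl8, a regulator of lipoprotein lipase, by 1.96 ± 0.16. Crp fell by 1.60 ± 0.16, from 193 ± 75.7 to 20.5 ± 3.96 in intensity. The induced levels of Crp and Angptl8 were below the 62.2 added before taking logs, on which the size of these falls depends. Falls were also measured for Rbpms (-1.90), AKR1C3l1 (-1.83), Bmp3 (-1.82), Akap7 (-1.60), Sema4a (-1.54), Anks4b (-1.50), Cyp4a8 (-1.42) and Pklr (-1.40). Gsta1 had the largest rise, 2.26 ± 0.14, followed by Glrx, a glutaredoxin, at 1.4 ± 0.25, while Ubd rose by 1.19 ± 0.22. Rises were also measured for Plcxd3 (1.25), Pik3r3 (1.24), Lims1 (1.08), Tmem87a (1.06), Pcmtd2 (1.06), Tmem150c (1.04), Oip5-as1 (1.03), Serpini1 (1.00) and Psme4 (0.98). For Oip5-as1 another probe set changed by 0.27 (limma adjusted p = 0.3) and another of Psme4 by 0.59 (adjusted p = 0.12). In limma 184 probe sets rose and 140 fell, 324 in all, and 33 were 2-fold changed in both clones, against a mean of 9.5 and a highest of 22 for pairs of different constructs. Counts fell whichever clone was left out, to 213 without clone 1a or 2b. There the P328L329del effects were unchanged and only the shared estimate of spread moved. Without clone 5a or 6a the effect rests on 1 clone and is less precise. Such losses do not by themselves show that calls depend on a particular clone. Without clone 6a 29 of the 39 named calls were lost, Myc and Crp among them, and without clone 5a 24. With no filter on dim probe sets 19 calls were left. Rises were 56.8% of the 324 calls, 48.2% of those with quantile normalization and 15.8% of those with no filter.

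With P328L329del 10 of 30 lists passed camera, 1 of them higher. Of 15 tested HNF1 targets 3 fell, Crp, Pklr and Slc2a2 (-0.72), and 0 rose (5 and 2 adjusted over the list alone, camera adjusted p = 0.039, adjusted p = 0.31 with an estimated correlation). Of 24 tested beta-cell genes 5 fell (9 adjusted over the list alone), Prlr (-1.23), Sytl4 (-1.12), Iapp (-0.74), Kcnj11 (-0.72) and Slc2a2 (camera adjusted p = 0.0043, adjusted p = 0.31 with an estimated correlation). Of the further probe sets, those below the threshold gave -0.48 for Prlr (limma adjusted p = 0.11) and -0.44 for Kcnj11 (adjusted p = 0.16). Of 5 islet hormone genes Gcg fell (-0.65), with 3 falls adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.31 with an estimated correlation). ER stress genes were lower as a list (camera adjusted p = 0.00023, adjusted p = 0.3 with an estimated correlation), though of 25 members only Creld2 passed (-0.97, 2 falls adjusted over the list alone). In the amino acid response 2 of 19 fell, Slc7a5 (-0.73) and Gars1 (-0.58), and 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00044, adjusted p = 0.3 with an estimated correlation). Mitosis genes were lower as a list (camera adjusted p = 6.1e-05, adjusted p = 0.3 with an estimated correlation), with 1 of 21 falling, the kinase Aurka (-0.49), and 5 adjusted over the list alone. DNA replication genes were lower too, with 1 of 22 falling on either adjustment, Mcm5 (-0.50, camera adjusted p = 0.0049, adjusted p = 0.31 with an estimated correlation). Of 29 mitochondrial ribosomal protein genes 3 fell, also adjusted over the list alone, Mrpl38 (-0.77), Mrpl12 (-0.67) and Mrps2 (-0.51, camera adjusted p = 0.017, adjusted p = 0.58 with an estimated correlation). Of 16 glycolysis genes Pklr fell (2 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.31 with an estimated correlation). The 13 interferon genes were higher as a list (camera adjusted p = 0.049, adjusted p = 0.54 with an estimated correlation), with 0 members passing in limma, also adjusted over the list alone. Quantile normalization ended the calls of glycolysis (camera adjusted p = 0.057) and mitochondrial ribosomal proteins (0.15). Without clone 6a 5 lists passed, the calls of islet hormones, glycolysis, mitochondrial ribosomal proteins, DNA replication and interferon genes being lost. Without clone 5a that of HNF1 targets was lost, and the interferon call also ended without clone 3b, 4a or 5a.

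Calls with wild-type HNF1b and with P328L329del, which share no arrays, overlapped in the same direction. Of the probe sets 65 rose with both, against 25.2 for independent calls, and 74 fell with both, against 23.9. Gsta1, Gsta4 and Ccng2, a cyclin, were among the shared rises, and Gcg, Iapp and Cyp4a8 among the shared falls. Opposite calls, which a shared spread would also raise, were near the independent number. Of these 22 rose with wild-type and fell with P328L329del (19.2) and 35 went the other way (31.4). Crp, Myc, Pklr and AKR1C3l1 were among the 22. Between clones of the same construct induction effects correlated across genes at r = 0.843 for wild-type, 0.537 for P328L329del and 0.367 for A263insGG, where genes are not independent replicates. Between clones of wild-type and P328L329del the r lay between 0.129 and 0.15. Between those of wild-type and A263insGG it was -0.013 and -0.027 with clone 3b and 0.169 and 0.164 with clone 4a, and between those of the mutants 0.131 and 0.099 with clone 3b and -0.073 and -0.028 with clone 4a.

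Induction of A263insGG lowered some of the genes that wild-type HNF1b raised. Cltrn fell from 1580 ± 201 to 450 ± 6.01 in intensity (SD, n = 2 clones), a log2 change of -1.68 ± 0.12 (SE, limma adjusted p = 0.0016). Crp fell by 1.53 ± 0.16 on the log2 scale, from 175 ± 13.6 to 19.9 ± 6.08 in intensity, and Nr1h4 by 1.47 ± 0.20, from 363 ± 3.39 to 92.8 ± 28. The induced level of Crp was below the 62.2 added before taking logs, on which the size of its fall depends. AKR1C3l1, of the aldo-keto reductase family, fell by 1.71 ± 0.11 and Gc, the vitamin D-binding protein, by 1.21 ± 0.13. Falls were also measured for Anks4b (-1.50), Akap7 (-1.49), Rcan2 (-1.40), St6gal1 (-1.33), Rnd3 (-1.28), Ddc (-1.15) and Cpn1 (-1.11), and the 1 probe set that rose was that of Sorbs3 (0.85 ± 0.12). Sorbs3 went from 84.6 to 202 in intensity, from a low uninduced level, against 226 in uninduced wild-type and 227 in uninduced P328L329del clones. Another Rcan2 probe set changed by -1.20 (limma adjusted p = 0.091). In all 17 probe sets fell and 1 rose, and 1392 had an unadjusted p below 0.05. By size alone 13 probe sets were 2-fold lower and 0 were 2-fold higher in both clones, a total above the mean of 9.5 but below the highest of 22 for pairs of different constructs. That 22 belonged to a wild-type and a P328L329del clone, and pairs of an A263insGG clone with another construct gave 1 to 10. Of the 17 falls 10 were rises with wild-type HNF1b (2.33 for independent calls) and 6 were falls with P328L329del (0.25), namely Akap7, AKR1C3l1, Anks4b, Cpn1, Crp and Ddc. Of the same 17, Akap7, Rcan2 and St6gal1 were among the falls with wild-type HNF1b (2.9 for independent calls), and Evi5 rose with P328L329del (0.329). The numbers for independent calls leave out that the constructs share 1 estimate of spread per probe set. Without clone 4a 0 calls were left in limma (477 at an unadjusted p below 0.05), without clone 3b 4, and without clone 1a or 2b 11. Of the 14 named calls AKR1C3l1, Anks4b and Akap7 kept theirs without clone 3b, and 11 were lost. Quantile normalization ended those of Sorbs3 (0.75, limma adjusted p = 0.055), Nr1h4 (-1.42, 0.052) and St6gal1 (-1.27, 0.055). With no filter on dim probe sets the limma count was 0 (1560 at an unadjusted p below 0.05).

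With A263insGG 5 of 30 lists passed camera. HNF1 target genes were lower, with 4 of 15 falling and 0 rising (7 falls adjusted over the list alone), Cltrn, Crp, Nr1h4 and Gc, whose list probe set changed by -1.04 (camera adjusted p = 1e-05, adjusted p = 0.37 with an estimated correlation). Of 7 tested genes of kidney tubules and cysts Cltrn fell (2 falls adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.7 with an estimated correlation). Genes of oxidative phosphorylation were higher as a list (median log2 change 0.20, camera adjusted p = 1e-05, adjusted p = 0.73 with an estimated correlation), though 0 of 36 passed in limma on either adjustment. Quantile normalization ended that call (camera adjusted p = 0.076). Cytosolic ribosomal protein genes were higher with the authors' scaling (camera adjusted p = 0.00058, adjusted p = 0.73 with an estimated correlation) and turned direction with quantile normalization (camera adjusted p = 0.64), with 0 of 26 passing in limma. Interferon genes were higher as a list (camera adjusted p = 0.026, adjusted p = 0.73 with an estimated correlation), with 0 of 13 passing over all tests and 3 rises and 1 fall adjusted over the list alone, and quantile normalization ended the call (camera adjusted p = 0.093). For the beta-cell list the median was 0.02, the mean -0.01 and the test direction higher without passing (camera adjusted p = 0.81), and 0 of 24 members passed in limma (0 rises and 1 fall adjusted over the list alone). Without clone 3b the ribosomal and kidney calls were lost, and without clone 4a that of the interferon list.

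The mean of the 3 induction effects was tested because no clone lacked a construct, and a large effect of 1 construct can carry it. The mean effect of Ubd was 2.23 ± 0.13 on the log2 scale (SE, n = 6 clones, limma adjusted p = 4.7e-05), made up of 5.65 with wild-type, 1.19 with P328L329del and -0.14 with A263insGG. That of Ccng2 was 1.16 ± 0.07, with 2.16, 0.97 and 0.34, and that of Nos2, the inducible nitric oxide synthase, 1.07 ± 0.30. Cyp4a8 had a mean effect of -1.66 ± 0.09, and it was the 1 probe set with a change of 1.5-fold or more in the same direction in 6 of 6 clones. Positive mean effects were also found for Car2 (1.55), Fhit (1.48), Folr1 (1.48), Ctsc (1.39), Cyp4f1 (1.38), Rup2 (1.28), Slc3a1 (1.24), Car5b (0.97) and Apcs (0.88). Negative mean effects were also found for Wnt4 (-1.50), Kcnj11 (-1.36), Stc1 (-1.32), Ddc (-1.28), Rbpms (-1.22), Akap7 (-1.21), Sytl4 (-1.20), Mest (-1.10), Zdhhc14 (-1.03), Spry1 (-1.02) and Maob (-1.02). In limma 927 probe sets were higher and 1003 lower, 1930 in all. With 1 induction term over the 6 clones, which counts the spread between constructs, 0 were called (1735 at an unadjusted p below 0.05). The lys control differed in the same way between induced and uninduced arrays of the 3 constructs, by -1.75 with wild-type, -1.37 with P328L329del and -1.95 with A263insGG on the log2 scale. Leaving out a clone gave 1018 calls without 1a, 1139 without 2b, 1012 without 4a, 1160 without 5a and 961 without 6a, and with no filter there were 1068.

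For the mean effect 14 of 30 lists passed camera. Of 24 beta-cell genes 16 had a negative and 2 a positive mean effect, also adjusted over the list alone (camera adjusted p = 2e-07, adjusted p = 0.24 with an estimated correlation), with -1.0 for Pdx1, -0.79 for Slc2a2 and -0.68 for Abcc8. The mean log2 change of Ins1, at the top of the scale, was 0.22 (limma adjusted p = 0.042), a call that was lost without each of the 6 clones and with quantile normalization (0.04). Of 19 heat shock genes 6 were lower (8 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.36 with an estimated correlation), and of 21 mitosis genes 5 were lower, on either adjustment (camera adjusted p = 0.0027, adjusted p = 0.3 with an estimated correlation). The HNF1 target list did not pass (camera adjusted p = 0.76), with 2 of 15 higher, Ttr (0.84) and Nr1h4 (0.44), and 2 lower, Slc2a2 and Crp (-0.32). Without clone 1a, 3b, 4a or 6a Crp lost its call, and Nr1h4 lost it without clone 1a, 2b, 3b, 4a or 6a. Crp took the opposite sign with an offset at the 40th percentile (0.09, limma adjusted p = 0.41). Cytosolic ribosomal protein genes were higher with the authors' scaling (camera adjusted p = 0.017, adjusted p = 0.37 with an estimated correlation) and turned direction with quantile normalization (camera adjusted p = 0.93), and a second Rps24 probe set was lower (-0.29, limma adjusted p = 0.033). The other lists lower for the mean effect were islet hormones (3 of 5), granins and exocytosis (10 of 24 lower, 1 higher), cholesterol synthesis (6 of 18), ER stress (10 of 25), the amino acid response (9 of 19) and DNA replication (7 of 22). Lists higher for the mean effect were oxidative phosphorylation (5 of 36), oxidative stress (7 of 21), interferon (7 of 13) and NF-kappaB genes (4 of 9). Adjusted over the list alone these counts were 3, 13 and 1, 8 (with 1 higher), 14 (with 2 higher), 10 and 8 lower, and 2, 8, 9 and 4 higher. Their camera adjusted p lay between 5e-05 and 0.017, and their adjusted p between 0.24 and 0.39 with an estimated correlation. Cholesterol synthesis lost its call without clone 3b, and ribosomal proteins without clone 3b or 5a.

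**Figure D4:**
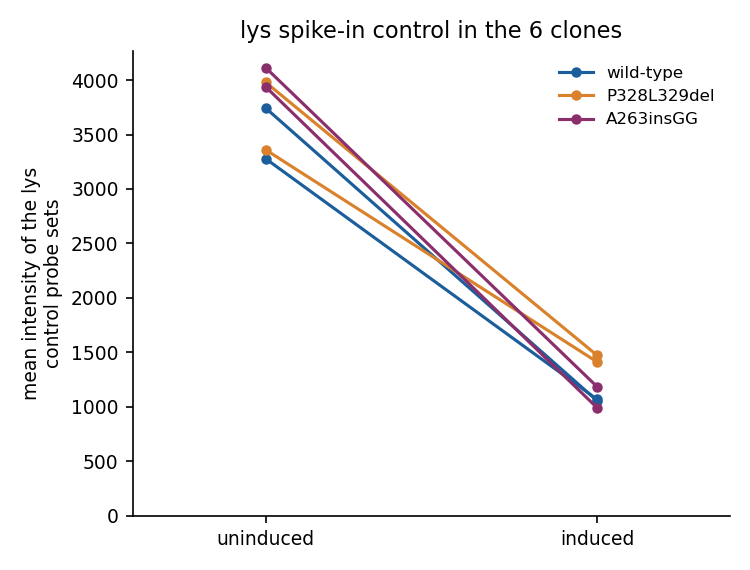
Mean intensity of the lys control probe sets on the uninduced and induced array of each clone, joined by a line per clone and coloured by construct. Uninduced arrays lay between 3278 and 4113 and induced arrays between 990 and 1472.

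The test of the difference between constructs asks whether a mutant changed a gene differently from wild-type HNF1b. How much of each construct was made on induction could not be read. A difference in that level was therefore not separated from a difference in what the construct does. The response of Car2 with P328L329del differed from that with wild-type by -4.90 ± 0.35 on the log2 scale (SE, limma adjusted p = 0.00014). That of Ubd differed by -4.46 ± 0.32, and that of Crp, which reversed from 2.18 to -1.60, by -3.77 ± 0.23. Fzd1 (-4.24), Folr1 (-4.15) and Ctsc (-3.84) completed the 6 largest negative differences. C2cd4b, which fell with wild-type, differed by 4.11 ± 0.15 in the opposite direction, as did Scn3a (4.07), Eef2k (3.22), Ngfr (3.02), Lmo3 (2.72) and Kcnj11 (2.58). Of 24 beta-cell genes 13 had positive differences (16 adjusted over the list alone, camera adjusted p = 1.7e-05, adjusted p = 0.33 with an estimated correlation), with 2.38 for Pdx1, 1.81 for Pax6 and 1.21 for Nkx6-1. Of 15 HNF1 targets 7 had a negative and 1 a positive difference (8 and 2 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.33 with an estimated correlation), with -2.51 for Cltrn, -2.27 for Pklr and -2.08 for Ttr. Granins and exocytosis genes had 10 positive and 1 negative of 24 (15 and 3 adjusted over the list alone, camera adjusted p = 0.0013, adjusted p = 0.33 with an estimated correlation). Of 9 NF-kappaB genes 5 had negative differences, on either adjustment (camera adjusted p = 0.002, adjusted p = 0.51 with an estimated correlation), with -1.14 for Nfkb2. Oxidative phosphorylation (camera adjusted p = 0.028, adjusted p = 0.59 with an estimated correlation) and cytosolic ribosomal protein genes (0.018, adjusted p = 0.57 with an estimated correlation) were lower as lists, calls that ended with quantile normalization (camera adjusted p = 0.37 and 0.56), without clone 2b and without clone 6a. In all 1682 probe sets differed, 1047 positively. Without clone 1a 784 did, without 2b 944, without 5a 900 and without 6a 766, and with no filter 883.

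For A263insGG the response of Ubd differed from that with wild-type HNF1b by -5.78 ± 0.32 on the log2 scale (SE, limma adjusted p = 4.3e-05) and Nr1h4 by -4.30 ± 0.28, with Car2 (-4.99), Folr1 (-4.87), Cyp4f1 (-4.42) and Fzd1 (-4.03). Positive differences were largest for C2cd4b (4.18), Ngfr (3.39), Wnt4 (3.32), Kcnj11 (3.24), Scn3a (3.07) and Pdx1 (3.06). Of 15 HNF1 targets 7 had negative differences, on either adjustment (camera adjusted p = 7.9e-06, adjusted p = 0.22 with an estimated correlation), with -3.71 for Crp, -3.69 for Cltrn and -1.87 for Ttr. Of 24 beta-cell genes 14 had a positive and 1 a negative difference (17 and 1 adjusted over the list alone, camera adjusted p = 2.6e-09, adjusted p = 0.22 with an estimated correlation), with 1.94 for Nkx6-1 and 1.57 for Abcc8. Of 5 islet hormone genes 2 had positive differences (5 adjusted over the list alone), Gcg (1.75) and Gast (0.97), with a camera adjusted p of 0.0028 (adjusted p = 0.34 with an estimated correlation). Of 24 granin and exocytosis genes 12 were positive and 3 negative (13 and 3 adjusted over the list alone, camera adjusted p = 7e-04, adjusted p = 0.22 with an estimated correlation), and of 25 ER stress genes 6 were positive and 1 negative (7 and 1 adjusted over the list alone, camera adjusted p = 0.0066, adjusted p = 0.28 with an estimated correlation). Of 21 oxidative stress genes 8 were negative and 2 positive, on either adjustment (camera adjusted p = 0.044, adjusted p = 0.45 with an estimated correlation), with -3.31 for Gsta1 and -2.26 for Gclc. NF-kappaB genes had 3 negative of 9 (4 adjusted over the list alone, camera adjusted p = 0.002, adjusted p = 0.34 with an estimated correlation). Kidney tubule genes had 3 of 7, on either adjustment (camera adjusted p = 0.044, adjusted p = 0.35 with an estimated correlation). That call ended with quantile normalization (camera adjusted p = 0.052) and without clone 1a, 3b, 5a or 6a, and the oxidative stress call without clone 2b, 3b, 5a or 6a. In all 1372 probe sets differed, 694 positively, with 769 without clone 1a, 816 without 2b, 871 without 3b, 833 without 4a and 856 with no filter.

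The mutants differed from each other in 68 probe sets, 15 of them with a positive difference of A263insGG minus P328L329del. Angptl8 differed by 2.37 ± 0.23 on the log2 scale (SE, limma adjusted p = 0.0098), with Sema4a (1.81), Myc (1.65), Rbpms (1.49), Ddc (1.45) and Mest (1.21). Gsta1 differed by -2.55 ± 0.20 (adjusted p = 0.0067), with Tmem87a (-2.04), Sema3c (-1.70), Evi5 (-1.68), Serpini1 (-1.57) and Fgfr4 (-1.56). Another Serpini1 probe set gave -1.04 (limma adjusted p = 0.082). In all 11 of 30 lists passed camera. They were those of beta-cell genes (1 of 24 higher with A263insGG, Iapp at 0.95, and 6 adjusted over the list alone), islet hormones (0 of 5, 3 adjusted over the list alone), glycolysis (Pklr of 16, also adjusted over the list alone) and immediate early genes (Myc of 17, 2 adjusted over the list alone). ER stress genes (0 of 25, 1 adjusted over the list alone), the amino acid response (0 of 19, 2 adjusted over the list alone), mitosis (0 of 21, 2 adjusted over the list alone), mitochondrial ribosomal proteins (0 of 29, 1 adjusted over the list alone) and oxidative phosphorylation (0 of 36, on either adjustment) also passed as lists with positive differences. Cytosolic ribosomal proteins did so with the authors' scaling (0 of 26) and turned direction with quantile normalization (camera adjusted p = 0.99). Kidney tubule genes had the 1 negative list difference, with Cltrn of 7 (-1.18, 2 adjusted over the list alone). The camera adjusted p of the 11 lists lay between 0.0043 and 0.048, and the adjusted p between 0.37 and 0.44 with an estimated correlation. Without clone 3b or 6a 0 lists passed camera, and fry called 0. Quantile normalization ended the calls of beta-cell genes (camera adjusted p = 0.12), glycolysis (0.076), oxidative phosphorylation (0.55), ER stress (0.24) and immediate early genes (0.057). For single probe sets 13 calls were left without clone 1a or 2b, 1 without clone 5a and 0 without clone 4a or 6a, with no filter 0 (1904 at an unadjusted p below 0.05 in limma), with no clone block 21 and with eBayes trend and robust settings 370. The named differences were lost without clone 4a or 6a in 15 of 15 cases.

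Uninduced clones were compared to see how the lines differed before induction, where clone-to-clone differences are part of any difference between constructs. Gcg was far higher in uninduced P328L329del clones, at 7790 ± 2700 in intensity (SD, n = 2 clones), than in wild-type clones, at 331 ± 42.1, a log2 difference of 4.28 ± 0.45 (SE, limma adjusted p = 0.0011). Igfbp2, a carrier of insulin-like growth factors, was higher by 3.35 ± 0.44, Tgfb2 by 2.81 ± 0.45 and Cck, cholecystokinin, by 1.98 ± 0.32. Maob, a monoamine oxidase, was lower by -2.47 ± 0.24 and Col9a1, a collagen chain, by -2.20 ± 0.18. Large differences were also measured for 6330403K07Rikl (2.14) and C1galt1 (1.85), and Dact2 (-2.05), St6gal1 (-1.92), Akap7 (-1.89) and Snx14 (-1.86). In all 278 probe sets were higher and 535 lower, 813 together. Of 17 immediate early genes 5 were higher (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 9e-04, adjusted p = 0.23 with an estimated correlation), such as Dusp6 (1.53) and Egr1 (1.33). Of 11 genes of TGF-beta and matrix 3 were higher (5 adjusted over the list alone, camera adjusted p = 0.0047, adjusted p = 0.23 with an estimated correlation), Tgfb2, Fn1 (1.13) and Fbln1 (0.55). Of 22 DNA replication genes 3 were lower (5 adjusted over the list alone, camera adjusted p = 0.043, adjusted p = 0.23 with an estimated correlation), such as Prim1 (-0.58). Of 21 oxidative stress genes Ephx1 was higher (1.04, also adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.55 with an estimated correlation). HNF1 targets and hormone genes that passed were Gast (1.35), Npy (-1.75), Gc (-1.64), Afp (-1.11) and Crp (-0.77), and beta-cell genes Prlr (-1.44), Ero1b (-1.26) and Gipr (-1.04). For Prlr another probe set gave -0.02 (limma adjusted p = 0.95) and a further one -0.81 (0.0061). Crp lost its call without each clone but 6a and with quantile normalization (-0.76, limma adjusted p = 0.053). Without clone 1a 255 calls were left, without 2b 114, without 6a 252 and with no filter 351. Of the 30 named calls 15 were lost without clone 2b, 10 without 1a and 5 to 7 without each other clone, that of Tgfb2 without 1a or 2b. The list call of DNA replication was lost without clone 5a and that of oxidative stress without 6a.

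Uninduced A263insGG clones differed from uninduced wild-type clones in 0 probe sets by limma, with 834 at an unadjusted p below 0.05. The 5 smallest p belonged to Tmem44 (-0.97), Fn1 (0.83), Gcg (2.82), Hcn2 (-0.82) and Sorbs3 (-0.97), each with a limma adjusted p of 0.076, which did not pass. As lists HNF1 targets were lower (camera adjusted p = 0.028, adjusted p = 0.58 with an estimated correlation) and ER stress genes higher (camera adjusted p = 0.028, adjusted p = 0.58 with an estimated correlation), with 0 members passing (1 fall and 0 adjusted over the list alone). The call of the HNF1 list ended with quantile normalization (camera adjusted p = 0.061) and without clone 1a, 2b, 3b or 4a, and that of ER stress without clone 1a, 2b or 3b. Cytosolic ribosomal protein genes were lower with the authors' scaling (camera adjusted p = 0.021, adjusted p = 0.99 with an estimated correlation), without a member passing in limma, and turned direction with quantile normalization (camera adjusted p = 0.78). Against uninduced P328L329del clones, 993 probe sets were higher and 720 lower in uninduced A263insGG clones, 1713 together. Maob was higher by 2.36 ± 0.24 on the log2 scale (SE, limma adjusted p = 0.00098), with Snx14 (2.03), Tmem87a (1.97), Pnisr (1.89), Thoc1 (1.80) and St6gal1 (1.77). Igfbp2 (-1.94), 6330403K07Rikl (-1.82), Gast (-1.80), Faim2 (-1.57), Dusp6 (-1.49) and Gcg (-1.46) were lower. Of 22 DNA replication genes 8 were higher, on either adjustment (camera adjusted p = 0.04, adjusted p = 0.29 with an estimated correlation), and of 11 TGF-beta and matrix genes 3 were lower (4 adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.29 with an estimated correlation). Of 17 immediate early genes 6 were lower and 1 higher (8 and 1 adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.49 with an estimated correlation). The count was 692 without clone 3b, 237 without 4a, 962 without 5a, 730 without 6a and 825 with no filter. Of the 31 named calls 18 were lost without clone 4a, 10 without 6a, 9 without 3b and 7 without 5a, and the list call of DNA replication was lost without clone 4a or 5a.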

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

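The tests of the lys control, and of scaling for the A263insGG falls and the uninduced P328L329del clones, were chosen only after the result was seen, while those of the uninduced level, of leak and of other splits were set before, except that the limit to 16 assignments for the mean effect came after.

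The response to induction differed between constructs by a test of the difference itself, with limma for probe sets and camera at a preset correlation for gene lists. For P328L329del minus wild-type 1682 probe sets and 6 gene lists differed (0 lists with an estimated correlation). The log2 differences were 4.11 for C2cd4b, 4.07 for Scn3a, 3.22 for Eef2k, 3.02 for Ngfr, 2.72 for Lmo3 and 2.58 for Kcnj11. On the other side they were -4.90 for Car2, -4.46 for Ubd, -4.24 for Fzd1, -4.15 for Folr1, -3.84 for Ctsc and -3.77 for Crp. For A263insGG minus wild-type 1372 probe sets and 8 lists differed (0 lists with an estimated correlation), with 4.18 for C2cd4b, 3.39 for Ngfr, 3.32 for Wnt4, 3.24 for Kcnj11, 3.07 for Scn3a and 3.06 for Pdx1. The negative differences were -5.78 for Ubd, -4.99 for Car2, -4.87 for Folr1, -4.42 for Cyp4f1, -4.30 for Nr1h4 and -4.03 for Fzd1. For A263insGG minus P328L329del 68 probe sets and 11 lists differed (0 lists with an estimated correlation and 0 with fry), with 2.37 for Angptl8, 1.81 for Sema4a, 1.65 for Myc, 1.49 for Rbpms, 1.45 for Ddc and 1.21 for Mest, and with -2.55 for Gsta1, -2.04 for Tmem87a, -1.70 for Sema3c, -1.68 for Evi5, -1.57 for Serpini1 and -1.56 for Fgfr4. Between the mutants 0 differences were left in limma without clone 4a or 6a, 1 without clone 5a and 13 without clone 1a or 2b, and 0 lists without clone 3b or 6a. Of the 2929 wild-type calls 1414 had a called difference against the wild-type direction with P328L329del, 1291 with A263insGG and 914 with both. These counts hold reversed changes as well as smaller ones, such as Myc (0.65 with wild-type and -1.88 with P328L329del). The 2929 were chosen on wild-type arrays that enter the difference, which favours this direction. The induced level of each construct could not be read, so it was not separated from the action of the mutants.

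The lys control, which belongs to no comparison of genes, was lower on the induced array of 6 of 6 clones, by -1.69 on the log2 scale, a signal in control data that no label mentions. A uniform loss of added RNA is argued against by the other 4 added controls, whose mean difference was -0.264, against an SD of 0.289 for lys over clones. That mean hides a split by construct. The 4 controls lay between -0.434 and -0.279 with wild-type, between 0.106 and 0.185 with P328L329del and between -0.633 and -0.513 with A263insGG. A difference in preparation between constructs was therefore not separated from the differences of induction effect. A preparation shared by the induced arrays is argued against as the source of the wild-type calls, since over the 2929 probe sets the mutants' median change in the wild-type direction was 0.06, with an SD of 0.03 over 4 clones, against 0.61 for wild-type. For changes common to the 6 clones it cannot be told apart from tetracycline or from an effect of the constructs, because these went together on every induced array. Such changes were 1002 probe sets with the same direction in 6 clones, 568 higher, against 772 if constructs were independent and the clones of a construct agreed as measured, and 0 of the 1002 reached 2-fold in 6 clones.

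The 17 falls with A263insGG included genes that wild-type HNF1b raised, such as Cltrn, Crp and Nr1h4. With quantile normalization the falls kept their size, with a median of -1.27 against -1.33 (SD 0.28 over the 17 probe sets). That test cannot decide on scaling as the cause. Array medians already lay between 326.9 and 370.6, so quantile normalization could hardly have removed falls of this size. A high level in the uninduced A263insGG clones is argued against as the whole cause, since they lay above the other 4 uninduced clones by a median of 0.45 (SD 0.35), less than the fall. Those 4 included the P328L329del clones, low in some of these genes. Uninduced Akap7 was at 4650 in A263insGG, 5410 in wild-type and 1460 in P328L329del clones, while Cltrn was at 1580, 1560 and 1930. Against uninduced wild-type clones alone 0 probe sets were called by limma. No mechanism was tested, and Hnf1a and Hnf1b had no named probe set. An effect of the construct stays open beside those of tetracycline and preparation, which were not separated from it, and without clone 4a limma gave 0 calls, without clone 3b 4 and without clone 1a or 2b 11.

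Uninduced P328L329del clones lay apart from the other uninduced clones, with 813 calls against wild-type, where Gcg was higher by 4.28 on the log2 scale. Quantile normalization gave 917 calls. That test cannot decide on scaling here either, because array medians already lay between 326.9 and 370.6. Leaky expression of the construct cannot be told apart from differences between clones, because the correlations across genes of one clone's uninduced difference with the other's induction effect were -0.165 and 0.122, with a mean of -0.021. Clones made separately differ in other ways, and with 2 clones per construct a difference between constructs and one between clones both stay open. The count was 255 without clone 1a, 114 without 2b and 252 without 6a.

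The mean effect was compared with exchanges of the induced and uninduced array within clones. Of the 32 assignments, the 16 that parted the wild-type clones gave 0 calls, because the wild-type effect then enters the residual, so they are no reference although they were counted in the plan. The real assignment, with 1930 calls, was 1 of the 16 that kept those clones together, which are too few for a share under 0.05, and the highest other gave 1546. With 1 induction term over the 6 clones the real split gave 0 calls in limma (1735 at an unadjusted p below 0.05), so 100 of 100 splits of 6 against 6 arrays, the real one included, gave as many by construction (highest other 8), which says nothing about chance.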

How the results depend on the processing

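Counts are of probe sets called unless lists are named, and 1 choice was changed at a time, except that the eBayes alternative switched on trend and robust together. Where no cause is given, the cause was not tested.

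With no filter, which tests more and dimmer probe sets, the counts were 19 for P328L329del, 0 for A263insGG (1560 at an unadjusted p below 0.05), 1068 for the mean effect, 883, 856 and 0 for the differences P328L329del minus wild-type, A263insGG minus wild-type and A263insGG minus P328L329del (1904 unadjusted for the last), and 351, 1 and 825 for the uninduced comparisons P328L329del against wild-type, A263insGG against wild-type and A263insGG against P328L329del. With a filter at the 60th percentile they were 33 for A263insGG, 107 for the difference between the mutants and 4 for uninduced A263insGG against wild-type. With no clone block, counts were 2362 for wild-type, 158 for P328L329del, 15 for A263insGG, 1393 for the mean effect and 1195, 1023 and 21 for the differences. Clone as a random block (consensus correlation 0.254) gave 491, 33 and 108 for P328L329del, A263insGG and the difference between the mutants, an offset at the 40th percentile 514, 55 and 192, and eBayes with trend and robust settings 622, 73 and 370. An offset of 1 gave 16 for the difference between the mutants. The mean effect had 0 calls with 1 induction term (1735 unadjusted), which adds the spread between constructs. No filter gave 50 P328L329del probe sets 2-fold changed in both clones, and a threshold of 1.5-fold gave 1156, 188 and 48 for wild-type, P328L329del and A263insGG.

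Leaving out 1 clone gave 1276 to 2866 for wild-type, 19 to 288 for P328L329del, 0 to 12 for A263insGG, 961 to 1551 for the mean effect, 766 to 1695, 769 to 1213 and 0 to 93 for the differences, and 114 to 632, 0 to 2 and 237 to 1464 for the uninduced comparisons. A construct left with 1 clone is assumed to vary like the others. Its effect is also less precise, so a lower count does not by itself show that calls rest on the clone left out.

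Of 30 lists, 0 were called in each comparison with an estimated correlation. fry, which tests a list by itself, called 23 for wild-type, 2 for P328L329del, 0 for A263insGG, 19 for the mean effect, 16, 17 and 0 for the differences and 6, 0 and 10 for the uninduced comparisons. With quantile normalization 2 lists were called for A263insGG, 5 for the difference between the mutants and 1 for uninduced A263insGG against wild-type. Leaving out 1 clone gave 9 to 12, 5 to 10, 3 to 5 and 12 to 14 lists for the inductions and the mean effect, 4 to 8, 6 to 9 and 0 to 11 for the differences and 4 to 7, 0 to 3 and 3 to 7 for the uninduced comparisons.

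Direction reversed for Crp in the mean effect with an offset at the 40th percentile (0.09, limma adjusted p = 0.41). It also reversed for cytosolic ribosomal proteins with quantile normalization, with camera adjusted p of 0.64 for A263insGG, 0.93 for the mean effect, 0.99 for the difference between the mutants and 0.78 for uninduced A263insGG against wild-type. Of 7123 recomputed values of 510 named gene results, 6211 kept direction and side of the threshold, 804 no longer passed and 107 newly passed. Of 837 for 77 list results, 623 kept both and 210 no longer passed. The mean r within constructs was 0.582, with 0.569 for an offset of 1, 0.633 for a filter at the 60th percentile and 0.58 for quantile normalization. Signal over background limits the dim probe sets, for which the offset of 62.2 shrinks log2 changes.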

Other observations

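The tests against random sets were chosen only after the result was seen, and so were the genes named in the next paragraphs.

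Some groups of genes moved in both directions with wild-type HNF1b and did not pass as lists in camera. Of 12 tested liver-enriched transcription factors 2 rose and 4 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.79), with log2 changes of 2.83 for Nr1h4 and 0.86 for Nr2f2, and of -1.03 for Dbp, -0.94 for Nr0b2 and -0.84 for Prox1. Their median was -0.05 and their mean 0.03. Of 18 amino acid and solute transporters 3 rose and 5 fell (3 and 7 adjusted over the list alone, 0.96), such as Slc1a1 (1.99) and Slc38a4 (-0.90), with a mean of 0.13 and a test direction of lower. Of 6 exocrine and duct markers Car2 (4.19) and Krt7 (1.74) rose and Bhlha15 (-1.49) fell, on either adjustment (0.57), with a median of -0.02 and a mean of 0.68. Of 16 adhesion genes 5 rose and 4 fell (5 and 5 adjusted over the list alone, 0.79), with 1.30 for Cdh2, N-cadherin, and -0.95 for Cdh1, E-cadherin. Among 11 genes of TGF-beta and matrix 2 rose and 1 fell, on either adjustment (0.16), Cdh2, Tgfb2 (0.79) and S100a4 (-1.07). Kidney tubule genes had 3 rises of 7, on either adjustment (0.18), Cltrn (2.02), Clcn5 (1.38) and Kif12 (0.42), and the 1 tested gene of immune and endothelial cells, Coro1a, fell (-1.07, 0.12).

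Genes of growth and metabolism were also mixed with wild-type HNF1b. Of 11 cell-cycle inhibitors and G1 cyclins 5 rose and 2 fell, on either adjustment (camera adjusted p = 0.16), with 2.16 for Ccng2, 0.96 for Cdkn1b and -0.99 for Ccnd2. Among 21 p53 targets 4 rose and 3 fell, on either adjustment (0.79, median -0.03 and mean 0.03), such as Gadd45a (1.77) and Gadd45g (-1.73), and of 17 immediate early genes 2 rose and 4 fell, on either adjustment (0.75), with 1.84 for Jun and -0.88 for Egr1. Falls without rises were measured in 6 of 21 mitosis genes, such as Bub1b (-0.78, 0.14), and in 5 of 19 heat shock genes, such as Hspa4 (-0.84, 0.084), both on either adjustment. Of 15 hypoxia genes 3 rose and 4 fell, on either adjustment (0.79), among them Vegfa (-1.18), with a mean of -0.01 and a test direction of higher. Of 16 glycolysis genes Pklr rose (1.07) and 3 fell, on either adjustment (0.57), with -1.22 for Eno2 and -0.87 for Ldhb. Fatty acid genes had 2 rises and 6 falls of 24, on either adjustment (0.46), such as Scd2 (-1.18) and Lpl (-0.74). TCA cycle genes had 3 rises and 3 falls of 23 (2 and 0 adjusted over the list alone, 0.90), with a median of -0.01 and a mean of 0.01, and mitochondrial ribosomal proteins 1 and 1 of 29 (0 and 1 adjusted over the list alone, 0.74).

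The mutants were also compared with the 241 wild-type rises of 2-fold or more, as counts of direction in both clones. With P328L329del 53.5% of them were higher in both clones, against a mean of 38.5% in 10000 random sets matched for intensity, and Gsta1 (2.26) and Ubd (1.19) were among them. With A263insGG 21.6% were higher in both clones, against a random mean of 32.7%. The other side of the same count was 42.7% lower in both A263insGG clones, against a random mean of 28.8%.

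Of the 15 tested HNF1 targets 12 were lower in both A263insGG clones, against a random mean of 3.92, and the list's camera adjusted p was 1e-05 (adjusted p = 0.37 with an estimated correlation). Cltrn changed by -1.81 and -1.54 in the A263insGG clones, and by 2.08 and 1.96 in the wild-type clones. Of the 17 A263insGG falls 12 were lower in both P328L329del clones, against a random mean of 4.68, and 6 of these 12 were calls with P328L329del. Anks4b changed by -1.50 with each mutant.

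Each of these counts except the 21.6% restates, on the same arrays, a pattern that had been seen in the calls, and random sets ignore correlation between genes. The random sets for the HNF1 targets and the A263insGG falls were matched on the same mean over all arrays, not on the level in the mutant clones. They describe the pattern and give no separate support to a hypothesis that the mutants share targets or act against wild-type HNF1b. The effect of tetracycline without a construct was not measured and stays open.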
